A study of Saccharomyces cerevisiae with 27 samples.

How the data were processed

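RNA from 27 budding yeast cultures was measured on Affymetrix expression arrays. Per the labels, cells grew at 30 °C in rich medium supplemented with an amino acid mix and were collected in exponential phase. Total RNA was taken with hot acid phenol, and biotinylated cRNA was made from 300 ng of it. The deposited values are intensity per probe set, made by the authors with RMA (background correction, quantile normalization and summarisation) in R 2.15.2, per the submitters' processing notes. The notes do not say whether the dates were normalized together, so any difference across dates can hold a difference in normalization. The planned tests assumed log2 values, but the deposited intensity was on a linear scale, from 10.373 to 39895, so log2 was taken before any test. Array medians ran from 1226.55 to 1276.5 intensity, and no depth exists for arrays, whose number limits the precision.

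The 27 arrays formed 9 groups of 3 replicate cultures, covering 8 genotypes on an earlier and a later experiment date. Wild type and eco1-W216G were run on the later date, the fob1 deletion on both, and all other strains on the earlier date. The series design names 6 strains, and the labels of the samples add a pair of strains that carry REC8 with mcd1 in the name. Each genotype came from 1 strain isolate, so the replicates show the spread between cultures, not between isolates. In the rad61 deletion, replicate 2 differed from replicates 1 and 3 over chromosome IX and in reporter probe sets. The spread of that group is therefore not only between like cultures. Of 5814 probe sets, 51 control and 47 reporter probe sets were left out and 5716 were tested. The platform's gene table gave exactly 1 gene symbol to 5498 of them and none to 218. The R64 gene table served only for names and for which genes are neighbours.

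Differences were tested with limma 3.58.1 in R 4.3.3, in 1 model of 9 group means with 18 residual degrees of freedom, two-sided, with Benjamini-Hochberg adjustment within each contrast and a threshold of 0.05. Where the groups compared came from different dates, the contrast subtracted the difference between the fob1 deletion arrays of the earlier and the later date. Values are log2 differences ± the limma SE, or group means ± SD, with n = 3 cultures per group throughout. The counts at an unadjusted p under 0.05 are given beside low counts.

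Gene lists were written beforehand: 41 lists with 1434 entries, of which 1362 matched a probe set, with 40 lists holding enough members to test. They were compared with all other genes by camera (limma) with a preset correlation of 0.01, adjusted over the lists within a contrast, and again with an estimated correlation. Where a gene had several probe sets, 1 was kept, which left 5449 genes. Chromosomes were tested in the same way. Member counts are given over all probe sets and adjusted over the list alone.

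The named genes follow a rule also fixed beforehand. It takes ECO1, FOB1, RAD61, MCD1 and REC8, the 10 highest and 10 lowest called differences per contrast with no overlap between the arrays (not asked of contrasts across dates), and up to 4 called members per list past the threshold. Of the names this rule gives, those printed were chosen after their values were visible. Genes beside FRE3 and URA3 were added after their values were visible.

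To compare the size of the eco1-W216G change between backgrounds, the change within the earlier date was regressed through the origin on the change within the later date, over the probe sets called in eco1-W216G against wild type. Selecting on 1 of the contrasts lowers such a slope, so slopes were also simulated 100 times at full retention. Each array also received a score, its position on the line from the wild-type mean, 0, to the eco1-W216G mean, 1.

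The model was tested on simulated data with 200 changed genes of 5716. It recovered 85 of 100 genes at 1.5-fold and 100 of 100 at 2-fold in eco1-W216G against wild type, with 7.04% false calls. For the rad61 deletion against wild type it recovered 65 and 90 with 6.06% false, and for the interaction of eco1-W216G and the fob1 deletion 65 and 91 with 8.77% false. The simulated noise was independent between arrays, with the same spread of a gene in every group. These rates thus do not cover arrays that share deviations or groups that spread more.

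The alternatives chosen before the data were examined were the date as a random block or left out, replicate number as a block, only the arrays compared, dim probe sets left out (4542 kept, 1174 removed), quantile normalization repeated, median centring, limma's trended and robust prior, and leaving out each array. Alternatives chosen after seeing the data were leaving out a pair of arrays that stand apart, another reference for the slopes, the rad61 slope without a replicate, and leaving out chromosome IX.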

Results

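Expression was measured in 27 cultures of yeast strains that differ in cohesin regulators. ECO1 encodes the acetyltransferase that establishes sister chromatid cohesion, FOB1 the replication fork barrier protein of the ribosomal DNA, and RAD61 the yeast homologue of the cohesin release factor Wapl. The strains were wild type, eco1-W216G, the fob1 and rad61 deletions, each deletion combined with eco1-W216G, and a pair of strains labelled as mcd1 mutants carrying REC8, the meiotic counterpart of the cohesin subunit Mcd1. Each group held 3 arrays. Correlations between arrays of a group ran from 0.986 to 0.998, and array medians from 1226.55 to 1276.5 intensity. The first principal component held 45% of the variance and the next 16.9%.

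The targeted genes ECO1, FOB1 and RAD61 had low signal in the strains labelled for them, and MCD1 did not. ECO1 signal was 4.61 ± 0.07 (log2, SD, n = 3) in eco1-W216G, 4.92 ± 0.17 in its fob1 double mutant and 4.80 ± 0.24 in its rad61 double mutant, against 7.85 ± 0.10 in wild type, although the label names a point mutation. FOB1 signal lay between 3.84 and 4.22 in the groups with a fob1 deletion, against 9.91 ± 0.04 in wild type. RAD61 signal was 3.93 ± 0.37 and 3.77 ± 0.08 in the groups with a rad61 deletion, against 7.24 ± 0.05 in wild type. MCD1 signal did not mark the strains labelled as mcd1 mutants, with 2050 ± 39.7 and 2070 ± 100.04 intensity against 2599 ± 86.9 in wild type and 2043 ± 123 in the rad61 deletion. REC8 was 5.70 ± 0.09 and 5.89 ± 0.09 there against 5.23 ± 0.18 in wild type and 5.66 ± 0.08 in eco1-W216G, so the lower of these did not stand apart, and the uracil synthesis gene URA3 was 13.33 ± 0.10 and 13.40 ± 0.05 against 11.20 ± 0.04. The positions of the array probes within these genes were not analysed here.

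The comparison of eco1-W216G with wild type, within the later date, asked what the acetyltransferase mutation changes in growing cells. Stress genes were far higher: HSP26, a small heat shock protein, rose by 4.42 ± 0.32 (log2, SE), 21.4-fold, and PIR3, a cell wall protein, by 4.42 ± 0.43. FIT3, a cell wall mannoprotein that retains siderophore iron, fell, with a difference of -5.30 ± 0.27. The similar gene FIT2 fell from 10.77 in wild type to 3.87 and the neighbouring ferric reductase gene FRE3 from 8.71 to 4.28, near the signal of deleted genes, so the size of these changes is only a lower bound. Most genes that make ribosomes were lower, but their list did not pass the threshold with an estimated correlation. Of 5716 probe sets, 3066 (53.6%) changed, 1354 up and 1712 down, of which 287 rose and 28 fell at least 2-fold.

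Of 71 targets of the stress factors Msn2 and Msn4, 69 rose and 0 fell (69 adjusted over the list alone), with a median of 1.22, adjusted p = 7.62e-34 and adjusted p = 0.0578 with an estimated correlation. They included HSP30 at 3.36, DDR2 at 3.25 and XBP1, a repressor induced by stress, at 3.12. Among heat shock chaperones 18 of 31 rose and 3 fell, the same counts adjusted over the list alone, with SSA4 at 2.20 and a median of 0.19 (adjusted p = 7.3e-05, and adjusted p = 0.391 with an estimated correlation). Mitochondrial and carbon genes rose too. In the tricarboxylic acid cycle 15 of 16 rose (16 adjusted over the list alone, median 0.66), with CIT3 at 1.47, SDH2 at 1.04 and CIT1 at 1.03, adjusted p = 1.1e-07 and adjusted p = 0.144 with an estimated correlation. Of 46 glucose-repressed genes 32 rose and 2 fell, the same adjusted over the list alone, with POT1, the peroxisomal thiolase, at 2.05 and MDH2 at 1.90 (adjusted p = 1.26e-07, and adjusted p = 0.322 with an estimated correlation). In the respiratory chain 33 of 42 rose, 33 adjusted over the list alone, with NDE2 at 1.25 (adjusted p = 6.34e-08, and adjusted p = 0.391 with an estimated correlation). The proteasome group rose as well, 31 of 35 genes (32 adjusted over the list alone, median 0.33), including its transcription factor gene RPN4 at 0.58 and the assembly factor UMP1 at 0.56, adjusted p = 3.05e-09 and adjusted p = 0.0578 with an estimated correlation.

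Growth genes went the other way. In ribosome biogenesis 126 of 146 genes fell and 0 rose (129 down adjusted over the list alone, median -0.49), with UTP4 at -0.95, NOP9 at -0.92 and ESF1 at -0.91. That list had adjusted p = 1.08e-14 and adjusted p = 0.391 with an estimated correlation. Aminoacyl-tRNA synthetases fell in 17 of 20 genes (17 adjusted over the list alone), with MES1 at -0.70 and CDC60 at -0.58. Translation factors fell in 25 of 36 (25 adjusted over the list alone), with the helicase DED1 at -0.99 and TIF4631 at -0.76. Subunits and factors of RNA polymerase I fell in 13 of 18 (14 adjusted over the list alone), with RPA34 at -0.50. These 3 lists had adjusted p = 6.12e-06, 1.42e-05 and 0.00559, and each had adjusted p = 0.391 with an estimated correlation. Of 127 cytosolic ribosomal protein genes 57 fell (49 adjusted over the list alone), with a median of -0.11 (adjusted p = 5.93e-06, and adjusted p = 0.539 with an estimated correlation).

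Several cell cycle and cohesion lists passed the threshold only with the preset correlation. Among genes of the G1 to S transition 34 of 61 fell and 3 rose, the same adjusted over the list alone (adjusted p = 0.000238, and adjusted p = 0.391 with an estimated correlation). Among 32 genes of the M to G1 transition 18 fell and 6 rose, the same adjusted over the list alone (adjusted p = 0.00888, and adjusted p = 0.391 with an estimated correlation). That group held BUD9, a bud site protein, at -1.46 and the daughter cell genes DSE1 at -1.31 and SCW11 at -1.27. Histone genes fell in 7 of 9 cases (7 adjusted over the list alone), with HTB2 at -0.69 (adjusted p = 0.00559, and adjusted p = 0.391 with an estimated correlation). Of 31 G2 to M genes of the CLB2 cluster 10 rose, with the kinase gene KIN3 at 1.01, and 5 fell, the same adjusted over the list alone (adjusted p = 0.0486, and adjusted p = 0.391 with an estimated correlation). Of 25 cohesin genes and regulators 12 fell and 2 rose (13 and 3 adjusted over the list alone), with CTF18, of an alternative clamp loader, at -0.79, the securin PDS1 at -0.59 and the cohesin core subunit SMC3 at -0.52 (adjusted p = 0.0185, and adjusted p = 0.391 with an estimated correlation). FOB1 itself fell by 0.67 (adjusted p = 0.000111). RAD61 fell by 0.44 (adjusted p = 0.0297), a call lost without eco1 replicates 1 or 3 or wild-type replicates 1 or 3, up to adjusted p = 0.106.

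**Figure D1:**
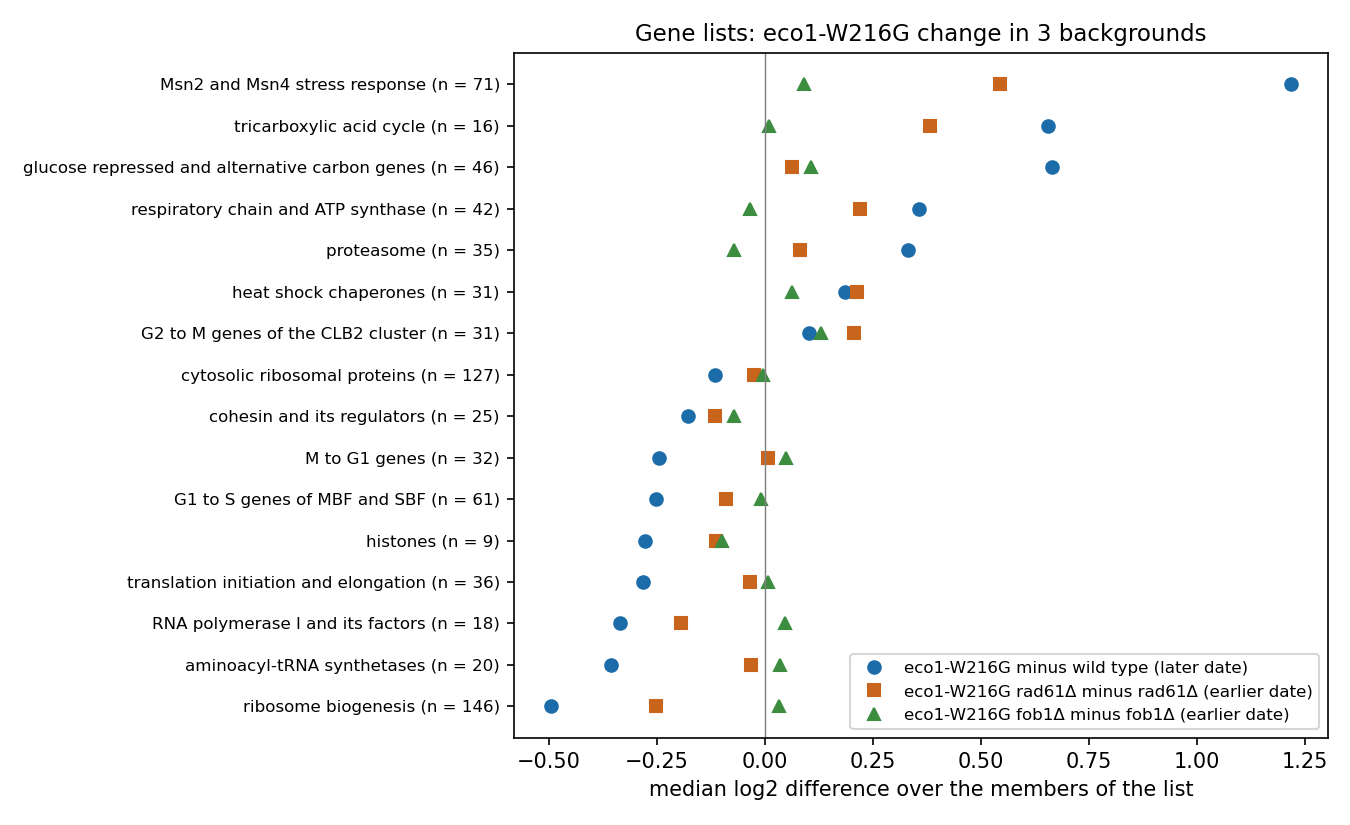
Median log2 difference of 16 gene lists for eco1-W216G in the wild-type background, without FOB1 and without RAD61. The Msn2 and Msn4 targets have medians of 1.22 with FOB1 and RAD61 present and 0.54 without RAD61, and ribosome biogenesis -0.49 and -0.25.

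Introducing eco1-W216G into the fob1 deletion, within the earlier date, asked how much of the mutant's change remains without FOB1. Few genes moved: 45 probe sets changed, 28 up and 17 down, with 637 at an unadjusted p under 0.05. With replicate number as a block the count was 99. Besides ECO1, which fell from 7.99 to 4.92, the surest change was NCA3, a SUN family gene, up by 1.62 ± 0.16. The cell wall gene HPF1 rose by 1.08 ± 0.16, and the acid phosphatase PHO3 by 0.77. Of 30 iron regulon genes 4 rose and 0 fell (16 up and 1 down adjusted over the list alone, median 0.27). They were the siderophore transporters SIT1 at 0.96, ARN1 at 0.79 and ARN2 at 0.79, and the reductase FRE2 at 0.92 (list adjusted p = 8.53e-11, and adjusted p = 0.201 with an estimated correlation). Of 27 oxidative stress genes, targets of Yap1, 2 fell (9 adjusted over the list alone). They were the exporter gene ATR1 at -1.13 and the glutathione transferase GTT2 at -1.10 (list adjusted p = 9.42e-09, and adjusted p = 0.195 with an estimated correlation). Cell wall genes rose in 3 of 32 cases (12 adjusted over the list alone), with GSC2 at 0.68 and TIP1 at 0.37 (adjusted p = 4.74e-07, and adjusted p = 0.387 with an estimated correlation). The CLB2 cluster rose in 4 of 31 (11 adjusted over the list alone), with CHS2 at 0.47 and CDC20 at 0.35 (adjusted p = 1.45e-06, and adjusted p = 0.173 with an estimated correlation). Every single-array omission moved the count by 1.5 times or more: it was 21, 24 and 25 without double mutant replicates 1, 2 and 3, and 30, 12 and 17 without fob1 replicates 1, 2 and 3. Of the genes named here only ECO1, NCA3, HPF1, PHO3 and TIP1 kept their call in all of these (up to adjusted p = 0.235 for ARN2), and median centring gave 26 up and 26 down.

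In the rad61 deletion, on the same date, eco1-W216G gave a larger response. FIT3 fell, with a difference of -5.84 ± 0.27, while FIT2 fell from 11.74 to 4.04 and FRE3 from 9.21 to 4.49, again near the signal of deleted genes. PIR3 rose by 1.94 and GAC1, a glycogen phosphatase subunit, by 1.79. Of 384 called probe sets 296 rose and 88 fell. With replicate number as a block 823 were called, 500 up and 323 down. Msn2 and Msn4 targets rose in 43 of 71 cases (54 adjusted over the list alone), with a median of 0.54 and GPH1, glycogen phosphorylase, at 1.32 (adjusted p = 3.68e-34, and adjusted p = 0.0522 with an estimated correlation). Tricarboxylic acid cycle genes rose in 10 of 16 (14 adjusted over the list alone), with CIT1 at 0.70 and SDH2 at 0.62 (adjusted p = 4.11e-12, and adjusted p = 0.0522 with an estimated correlation). Heat shock chaperones rose in 10 of 31 (14 adjusted over the list alone), with HSP104 at 0.67 (adjusted p = 4.87e-10, and adjusted p = 0.113 with an estimated correlation). CLB2 cluster genes rose in 10 of 31 and fell in 1 (14 and 2 adjusted over the list alone), with KIN3 at 0.74 (adjusted p = 4.69e-08, and adjusted p = 0.0545 with an estimated correlation). Ribosome biogenesis had a median of -0.25 with 5 of 146 genes down (0 adjusted over the list alone), by limma and camera, with adjusted p = 1.22e-18 and adjusted p = 0.494 with an estimated correlation. The count was 182 with only the arrays compared, 198, 183 and 209 without double mutant replicates 1, 2 and 3, 553 (361 up and 192 down) without rad61 replicate 2, in which chromosome IX was higher (median 0.82, 187 of 191 genes), 355 (292 up and 63 down) without chromosome IX, and 906 (541 up and 365 down) without both rad61 replicate 2 and later-date fob1 replicate 2. HSP26, up by 1.10 (adjusted p = 0.0412), lost its call without any of the 6 arrays but rad61 replicate 2, up to adjusted p = 0.192.

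The interaction terms compared the eco1-W216G change directly between backgrounds. Without FOB1, the change differed at 2238 probe sets, 1209 higher and 1029 lower; without RAD61, at 1341, 677 higher and 664 lower. The response of HSP26 differed by -4.19 ± 0.45 without FOB1 and by -3.32 ± 0.45 without RAD61. For the Msn2 and Msn4 list the median difference was -1.20 without FOB1, with 67 of 71 genes lower (67 adjusted over the list alone, and adjusted p = 0.0612 with an estimated correlation). It was -0.72 without RAD61, with 46 lower (51 adjusted over the list alone, and adjusted p = 0.139 with an estimated correlation). Ribosome biogenesis was higher by a median of 0.50 without FOB1, in 91 of 146 genes (97 adjusted over the list alone, and adjusted p = 0.464 with an estimated correlation). Without RAD61 it was higher by 0.26, in 26 genes (25 adjusted over the list alone, and adjusted p = 0.654 with an estimated correlation). The FIT3 response differed by 5.79 without FOB1. Over the 3066 probe sets of eco1-W216G against wild type, the slope of the change without FOB1 was 0.0531 (jackknife SE 0.0461), with 47.4% keeping their sign. It was 0.0248 and 0.0833 without fob1 double mutant replicates 2 and 3, 0.0817 and 0.0296 without earlier-date fob1 replicates 2 and 3, and 0.0316 without dim probe sets. It was highest with the later-date fob1 deletion in place of wild type as reference, a setting chosen after seeing the data. Without RAD61 the slope was 0.330 (SE 0.0558), with 79.8% keeping their sign, against a mean of 0.968 simulated at full retention. Of the 384 calls without RAD61, 331 were also called in the wild-type background, 330 in the same direction. These were 269 up and 61 down, against 70.1 and 26.4 expected from the counts. Of the 45 calls without FOB1, 30 and 22 were, with 18 up and 4 down against 6.63 and 5.09 expected. Two-sided Fisher's exact tests of the calls gave p = 1.44e-44 and p = 0.098. They ignore direction and take probe sets as independent, so they do not measure the spread between cultures. The eco1-W216G and wild-type arrays come from the later date and both double mutant comparisons from the earlier one.

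**Figure D2:**
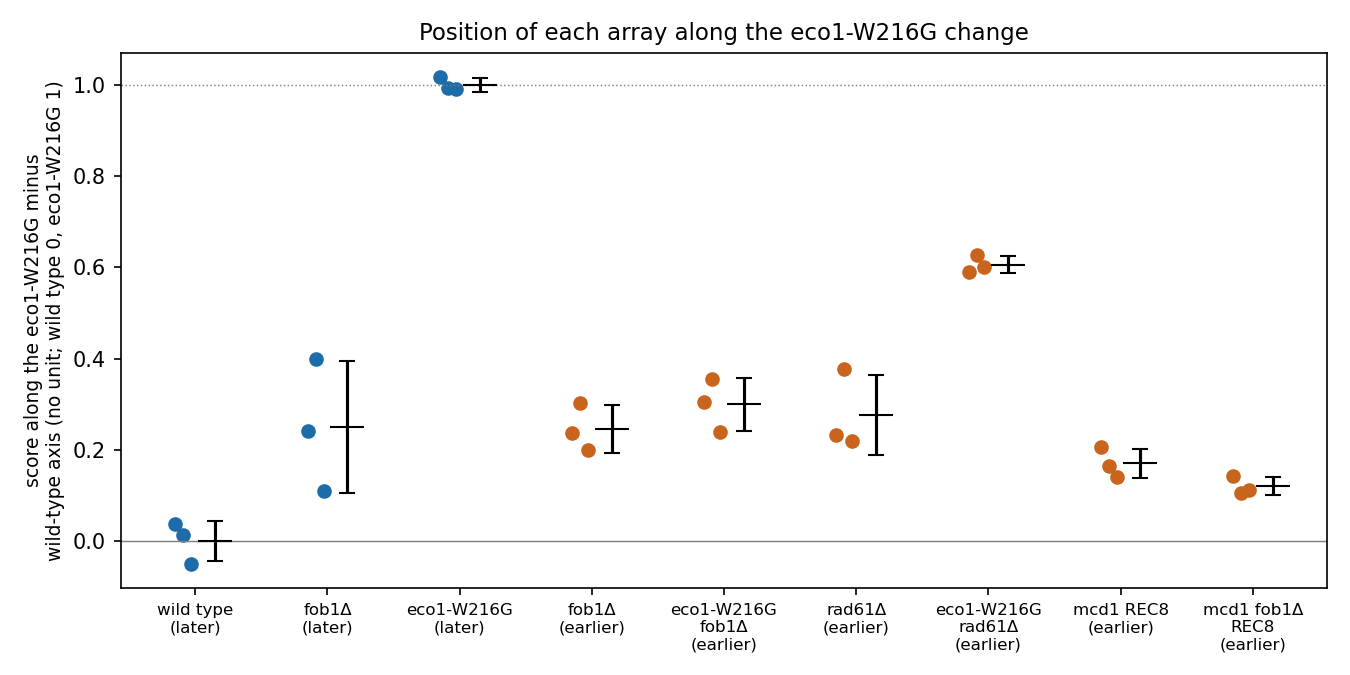
Position of each of the 27 arrays on the line from the wild-type mean (0) to the eco1-W216G mean (1), as points with group mean and SD, n = 3, later date in blue and earlier date in orange. The end groups are fixed by construction. The rad61 double mutant averages 0.606 and the rad61 deletion of the same date 0.276. The fob1 double mutant averages 0.30, the fob1 deletion of the same date 0.246 and the later-date fob1 deletion 0.25. The scores are not corrected for the date.

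The double mutants were next compared with eco1-W216G, with the date difference subtracted, to ask what removing FOB1 or RAD61 changes in the mutant. Stress genes were lower without FOB1: SIP18, a desiccation protein, was at -3.24, HSP26 at -2.86 and DDR2 at -2.49. FIT2 and FRE3 were higher, at 12.30 and 9.31 against 3.87 and 4.28 in eco1-W216G, where both lay near the signal of deleted genes. Of 1519 called probe sets 852 rose and 667 fell. Msn2 and Msn4 targets fell in 60 of 71 cases (64 adjusted over the list alone), adjusted p = 6.03e-33 and adjusted p = 0.0601 with an estimated correlation. Respiratory chain genes fell in 29 of 42 (33 adjusted over the list alone), with SDH2 at -1.06, adjusted p = 9.55e-16 and adjusted p = 0.159 with an estimated correlation. The proteasome list fell in 25 of 35 (28 adjusted over the list alone, median -0.36), adjusted p = 1.33e-13, and held with adjusted p = 0.0211 with an estimated correlation. M to G1 genes rose in 13 of 32 and fell in 2 (15 and 2 adjusted over the list alone), with BUD9 at 1.58 and SCW11 at 1.40 (adjusted p = 5.41e-05, and adjusted p = 0.159 with an estimated correlation). Without RAD61, 544 probe sets changed, 300 up and 244 down, and 966 changed with replicate number as a block. SIP18 fell by 2.25 (adjusted p = 0.0169) and DDR2 was at -1.76. M to G1 genes rose in 12 of 32 and fell in 1 (14 and 1 adjusted over the list alone), with SCW11 at 1.26 and DSE1 at 1.24 (adjusted p = 1.19e-07, and adjusted p = 0.0648 with an estimated correlation). The proteasome list fell in 11 of 35 (20 adjusted over the list alone, median -0.25), adjusted p = 4.69e-12, and held with adjusted p = 0.0348 with an estimated correlation. Without the date term the counts were 2908 and 2001, and the second count was 1091 with the date as a random block, 1088 without rad61 replicate 2 and later-date fob1 replicate 2, 329 (147 up and 182 down) with only the arrays compared, 511 (250 up and 261 down) with median centring, 309 without eco1 replicate 3, 326 without rad61 double mutant replicate 2, 325 and 310 without earlier-date fob1 replicates 1 and 2, and 955 without later-date fob1 replicate 2. SIP18 without RAD61 lost its call without earlier-date fob1 replicate 1 (adjusted p = 0.0509).

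The double mutants were also compared with wild type across dates. In the fob1 double mutant 101 probe sets changed, 69 up and 32 down, with PIR3 at 2.75 (adjusted p = 0.0228), NCA3 at 1.18 and RPA34, an RNA polymerase I subunit, at -0.66. With replicate number as a block 601 changed. Of 146 ribosome biogenesis genes 1 fell (16 adjusted over the list alone, median -0.32), and of 71 Msn2 and Msn4 targets 5 rose (29 adjusted over the list alone, median 0.41), each list with adjusted p = 0.585 with an estimated correlation. In the rad61 double mutant 929 changed, 612 up and 317 down, and 1433 changed with replicate number as a block. PIR3 rose by 3.83, HSP26 by 2.70 and GAC1 by 2.59. FIT2, FIT3 and FRE3 were lower, at 4.04, 7.18 and 4.49 against 10.77, 12.09 and 8.71 in wild type. There the Msn2 and Msn4 targets rose in 53 of 71 cases (60 adjusted over the list alone, median 0.87), ribosome biogenesis genes fell in 66 of 146 (100 adjusted over the list alone, median -0.50), and tricarboxylic acid cycle genes rose in 12 of 16 (13 adjusted over the list alone, median 0.53). Their adjusted p = 0.135, adjusted p = 0.419 and adjusted p = 0.135 with an estimated correlation. The first count was 40, 30 and 208 without double mutant replicates 1, 2 and 3, 176, 48 and 21 without wild-type replicates 1, 2 and 3, 47 and 35 without earlier-date fob1 replicates 1 and 3, and 429 without later-date fob1 replicate 3; PIR3 lost its call without double mutant replicates 1 or 2, earlier-date fob1 replicates 1 or 3 or wild-type replicate 3 (up to adjusted p = 0.0688). The second was 534 without wild-type replicate 3, the counts were 1944 and 2412 without the date term and 797 and 1586 with the date as a random block, and for the first only the arrays compared gave 8, leaving out rad61 replicate 2 and later-date fob1 replicate 2 gave 152, repeated quantile normalization gave 45 up and 35 down and median centring 58 up and 44 down.

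**Figure D3:**
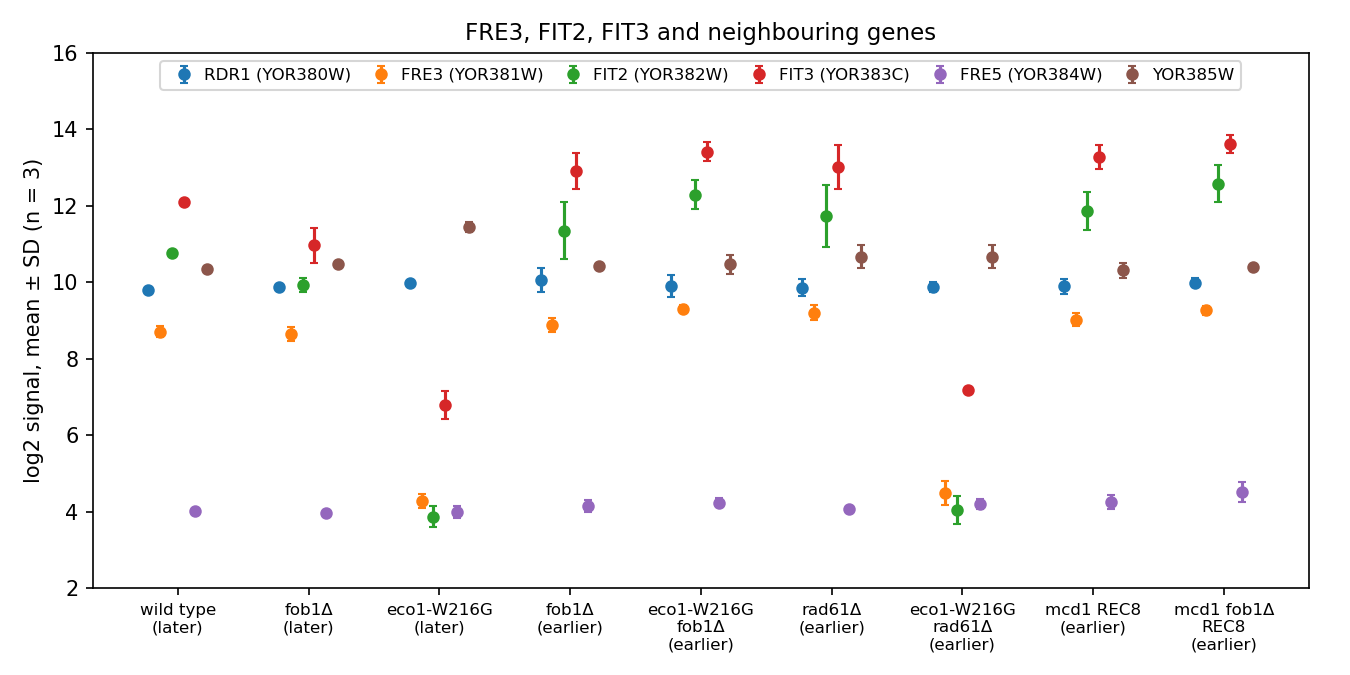
Log2 intensity (mean and SD, n = 3) of RDR1, FRE3, FIT2, FIT3, FRE5 and YOR385W, neighbours in that order, in the 9 groups. FRE3 is at 4.28 and 4.49 in eco1-W216G and its rad61 double mutant and at 8.71 in wild type, while RDR1 stays between 9.79 and 10.06.

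The fob1 deletion was compared with wild type within the later date, to ask what loss of the fork barrier protein does alone. FOB1 fell from 9.91 to 3.84, and the drug exporter AZR1 fell by 1.74 ± 0.28. Some genes for making ribosomes were lower and some stress genes higher, but neither list passed the threshold with an estimated correlation. In all 894 probe sets changed, 499 up and 395 down, of which 7 rose and 5 fell at least 2-fold. With replicate number as a block the count was 1437. Ribosome biogenesis genes fell in 73 of 146 cases (99 adjusted over the list alone, median -0.36), with NOP53 at -0.80 (adjusted p = 7.67e-31, and adjusted p = 0.912 with an estimated correlation). RNA polymerase I genes fell in 4 of 18 (6 adjusted over the list alone), with RPA34 at -0.62 (adjusted p = 0.000565), and ribosomal protein genes in 26 of 127 (34 adjusted over the list alone, adjusted p = 3.81e-11), each with adjusted p = 0.912 with an estimated correlation. Msn2 and Msn4 targets rose in 22 of 71 (29 adjusted over the list alone, median 0.28), with HSP26 at 1.33 (adjusted p = 1.87e-09 for the list, and adjusted p = 0.912 with an estimated correlation). Mitochondrial ribosomal protein genes rose in 16 of 71 (18 adjusted over the list alone), with MRPL8 at 0.63 (adjusted p = 0.000201, and adjusted p = 0.912 with an estimated correlation); without the arrays that stand apart that median was -0.055. Later-date fob1 replicate 2 deviated most from its group of all arrays, by 0.235 (root mean square, log2). The count was 588 and 492 without fob1 replicates 1 and 2, 507 and 2.2e+02 without wild-type replicates 2 and 3, and 1 when only the 6 arrays compared were modelled. HSP26 reached adjusted p = 0.0584 without fob1 replicate 2, and AZR1, NOP53, RPA34 and MRPL8 kept their calls without any single array.

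The rad61 deletion was compared with wild type across dates, to ask what loss of the release factor does alone. RAD61 fell, with 3.93 against 7.24 in wild type. In the fit without a replicate block 18 probe sets changed, 13 up and 5 down, with 931 at an unadjusted p under 0.05. With replicate number as a block the count was 199. TFS1, an inhibitor of carboxypeptidase Y, rose by 0.79 (adjusted p = 0.0412), and ACS1, acetyl-CoA synthetase, by 0.57 (adjusted p = 0.0412). CTF18 fell by 0.75 (adjusted p = 0.0423), the repair scaffold gene RTT107 fell by 0.73 (adjusted p = 0.0483) and the vesicle transport gene USO1 fell by 0.69 (adjusted p = 0.0248). Ribosome biogenesis had a median of -0.25 with 0 of 146 genes called by limma (0 adjusted over the list alone). Msn2 and Msn4 targets had a median of 0.33 with 1 of 71 up (9 adjusted over the list alone). Camera gave adjusted p = 3.04e-15 and 9.45e-11, and each had adjusted p = 0.742 with an estimated correlation. In rad61 replicate 2, genes of chromosome IX were higher than in replicates 1 and 3 by a median of 0.82, with 187 of 191 above 0, while the other 15 chromosomes had -0.05. Every call named here but RAD61 was lost in some single-array omission, up to adjusted p = 0.141 for RTT107. The count was 6, 1 and 2 without rad61 replicates 1, 2 and 3, 5, 3 and 1 without wild-type replicates 1, 2 and 3, 1 and 1 without earlier-date fob1 replicates 1 and 3, 11, 2 and 2.2e+02 without later-date fob1 replicates 1, 2 and 3, 2 (0 up and 2 down) with either rescaling, 1 with only the arrays compared, 5 with the trended robust prior, 3 without both rad61 replicate 2 and later-date fob1 replicate 2, 377 (187 up and 190 down) with the date as a random block and 1612 (758 up and 854 down) without the date term.

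The strains labelled as mcd1 with REC8 were compared with wild type and with each other, although MCD1 signal did not mark them. Against wild type, across dates, the strain labelled mcd1 with REC8 had 4 changed probe sets, 3 up and 1 down, with 916 at an unadjusted p under 0.05. With replicate number as a block the count was 243 (116 up and 127 down). URA3 rose by 1.99 ± 0.12, the kinase gene RCK1 by 0.78 (adjusted p = 0.00354) and YMR262W by 0.57 (adjusted p = 0.0474), and RPA34 fell by 0.65 (adjusted p = 0.0474). Ribosome biogenesis had a median of -0.26, with 0 of 146 called by limma (1 adjusted over the list alone, and adjusted p = 0.902 with an estimated correlation). Deleting FOB1 in that strain changed 1 probe set, FOB1 itself, which fell from 9.63 to 4.22, with 173 at an unadjusted p under 0.05. The effect of the fob1 deletion differed between these strains and wild type at 396 probe sets, 197 higher and 199 lower, with AZR1 at 1.76 (adjusted p = 0.0171), CGR1, a ribosome biogenesis gene, at 1.10 and HSP26 at -1.60. With replicate number as a block it differed at 959. The fob1 deletion and wild type were compared within the later date and the REC8 pair within the earlier one, so strain and date cannot be told apart. The ribosome biogenesis list differed by a median of 0.47, in 48 of 146 genes (92 adjusted over the list alone, and adjusted p = 0.561 with an estimated correlation). That count was 201 and 872 without later-date fob1 replicates 1 and 3, 64 without REC8 fob1 replicate 3, 250 and 144 without REC8 replicates 1 and 2, 212 and 68 without wild-type replicates 2 and 3, and by limma 0 with only the arrays compared (1253 at an unadjusted p under 0.05), and CGR1 and HSP26 reached adjusted p = 0.12 and 0.0896. The count of 4 was 172 and 17 without later-date fob1 replicate 3 and wild-type replicate 1, 2 without any other of its 12 arrays except later-date fob1 replicates 1 and 2, 3 (1 up and 2 down) with repeated quantile normalization, 1 without dim probe sets, 8 without rad61 replicate 2 and later-date fob1 replicate 2, 251 (100 up and 151 down) with the date as a random block and 1401 (653 up and 748 down) without the date term; YMR262W and RPA34 were lost in some of these.

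The fob1 deletion was grown on both dates, which measured the difference between dates. FIT3 and FIT2, the siderophore mannoproteins, were higher on the earlier date by 1.96 (adjusted p = 0.000764) and 1.42 (adjusted p = 0.0293), and the acid phosphatase PHO5 by 0.99 (adjusted p = 0.00119). CIS1 was lower by -2.21 (adjusted p = 0.0218) and YGR035C by -1.68 (adjusted p = 0.0047). In all, 104 probe sets were higher and 171 lower. Methionine genes were higher in 11 of 26 cases (15 adjusted over the list alone, median 0.46), with MET2 at 0.72 (adjusted p = 0.143 with an estimated correlation). Phosphate regulon genes were higher in 5 of 19 (8 adjusted over the list alone, and adjusted p = 0.143 with an estimated correlation). Mitochondrial ribosomal protein genes were lower in 13 of 71 (34 adjusted over the list alone, median -0.28, and adjusted p = 0.470 with an estimated correlation). The count was 91, 40 and 173 without earlier-date replicates 1, 2 and 3 and 81 and 447 without later-date replicates 2 and 3, and FIT2, MET2 and CIS1 lost their calls in such omissions (up to adjusted p = 0.144, 0.0811 and 0.0867). Repeated quantile normalization gave 206 differences, 101 of them lower, median centring 141 and 88, leaving out later-date replicate 2 and rad61 replicate 2 119, and only the arrays compared 0 by limma (799 at an unadjusted p under 0.05).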

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

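The splits of the arrays and every test of an explanation in this part were chosen after the results were seen.

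The effect of eco1-W216G differed between backgrounds in direct tests of the difference. Without FOB1 it differed at 2238 probe sets: HSP26 by -4.19, TMA10 by -3.01, CIT3 by -1.20, UMP1 by -0.62, NOP9 by 1.09, MES1 by 0.79, FIT3 by 5.79 and BUD9 by 1.46, and as measured FIT2 by 7.84 and FRE3 by 4.86, sizes that rest on eco1-W216G signals near those of deleted genes. The list medians differed by -1.20 for Msn2 and Msn4 targets, -0.68 for the tricarboxylic acid cycle, -0.39 for the proteasome, 0.50 for ribosome biogenesis and 0.36 for aminoacyl-tRNA synthetases. Without RAD61 it differed at 1341 probe sets: HSP26 by -3.32, POT1 by -2.09, BUD9 by 1.15, NOP9 by 0.80 and MES1 by 0.60. The list medians there were -0.72 for Msn2 and Msn4 targets, -0.21 for the proteasome, 0.26 for ribosome biogenesis and 0.32 for aminoacyl-tRNA synthetases. No list difference held with an estimated correlation. The effect of the fob1 deletion differed between the REC8 strains and wild type at 396 probe sets: HSP26 by -1.60, AZR1 by 1.76 and CGR1 by 1.10, with list medians of 0.47 for ribosome biogenesis and -0.44 for Msn2 and Msn4 targets.

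The smaller eco1-W216G change in the fob1 and rad61 deletion backgrounds was weighed against the date, which separates the arrays with the full change from both double mutants. A signal scale compressed on the earlier date stays open: the ECO1 drop kept 0.946 of its later-date size, but ECO1 stood at or below percentile 3.78 in those arrays, too near the floor to decide, and FIT3, which changed by -5.84 in the rad61 background and -5.30 on the later date, is a single gene of the largest changes. The date as the whole cause would shrink both backgrounds alike on the earlier date. Yet their slopes differed by 0.277 (SE 0.0724, which combines their jackknife SEs as if independent, although they share the eco1-W216G and wild-type arrays). No single array decides this, since without any array the slope stayed at or below 0.0833 without FOB1 and at or above 0.301 without RAD61. The smaller change itself did not rest on a single array either, since the highest slope without an array was 0.381. Date-specific culture conditions behind the part common to both backgrounds cannot be told apart from the deletions, since 0 arrays of eco1-W216G were run on the earlier date. Fob1 and Rad61 activity may contribute unequally to the mutant's expression change, which is an untested hypothesis for the difference between the backgrounds and leaves the date and its signal scale open for their common part. The fob1 double mutant also differed otherwise from eco1-W216G and the rad61 double mutant. It kept FRE3 at 9.31 against 4.28 and 4.49, and a reporter probe set was at 4.31 against 12.97 and 12.38. A further difference of that strain cannot be told apart from the fob1 deletion.

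The low FRE3, FIT2 and FIT3 signal in eco1-W216G and its rad61 double mutant was weighed next; these genes are neighbours. A fall of the whole iron regulon would take other members along, yet 0 of the 26 other members fell by as much as the least changed of the 3, and their median was -0.03 against wild type and -0.06 against the rad61 deletion. Loss of the genes from both strains could give such a signal: FRE3 and FIT2 stood at or below percentile 2.97 of their arrays. FIT2 reached percentile 1.54 in eco1-W216G and 2.36 in its rad61 double mutant, and FRE3 2.13 and 2.97. The highest for deleted genes were 2.01 for FOB1 and 2.08 for RAD61. FIT2 in eco1-W216G thus lay no higher than these levels, and the others reached slightly above them. FIT3 stood as high as percentile 9.41, further above those levels. These percentiles come from different probe sets, so they do not decide loss for any of the 3. A lost gene and a silenced gene cannot be told apart from expression alone. In the fob1 double mutant the 3 genes kept signals of 9.31, 12.30 and 13.42, and no biological explanation was tested.

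The many calls in the fob1 deletion against wild type and the few in the REC8 strains were weighed last. A single effect of the fob1 deletion in every strain would give a slope near 1 over the 893 probe sets, less what selection takes. The slope in the strains labelled with REC8 was -0.189 (jackknife SE 0.110). That slope does not decide the question, since the lowering by selection was not simulated for these probe sets. The fob1 and wild-type arrays are also of the later date and the REC8 pair of the earlier one, so strain and date cannot be told apart. A single array as the whole cause was weighed by leaving out each array, and the lowest count was 2.2e+02. Those fits took the spread from all groups. The later-date fob1 arrays deviated from their group by 0.131, 0.235 and 0.159, against 0.0929, 0.0750 and 0.0980 for wild type. With only the arrays compared, the count was 1. The lowest count thus does not decide whether noisy arrays gave the calls. Wild-type arrays that stand apart from all other strains fit the slope of -0.104 (SE 0.104) for the rad61 deletion minus the fob1 deletion, and of -0.112 (SE 0.0816) for the REC8 strain minus the fob1 deletion, on the fob1 change. The same slopes would arise if the rad61 and REC8 strains changed like the fob1 deletion, so a difference of the strains may be as good an account, and this stays open. Wild type is also the reference for eco1-W216G, for its interactions and for comparisons across dates. On the line to eco1-W216G, the groups without that mutation averaged from 0.121 to 0.276, all above wild type. A wild-type offset could enter those results too. For the slopes, the later-date fob1 deletion was used as reference in place of wild type, a setting chosen after seeing the data. Both slopes stayed within 1 jackknife SE. For the other results an offset was not tested.

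Other splits of the same arrays were tested as a measure of chance. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05; the real split was the only 1 with as many calls, at 3066 for eco1-W216G against wild type, 894 for the fob1 deletion against wild type, 45 and 384 for eco1-W216G in the fob1 and rad61 deletions, 1 for the fob1 deletion in the REC8 strains and the 104 higher and 171 lower between dates, with a highest other count of 0 in each. Where more splits exist, 100 were taken. The share of all splits was under 0.05 for the fob1 double mutant against eco1-W216G (2 splits with as many calls as the real 1519, highest other 1735), the same strain against wild type (3 with as many as 101, highest other 446), the rad61 double mutant against wild type (1 with as many as 929, highest other 562), the interaction of eco1-W216G and the fob1 deletion (3 with as many as 2238, highest other 2495) and that of the fob1 deletion and REC8 (2 with as many as 396, highest other 499). It was 0.05 or more for the rad61 deletion against wild type (7 with as many as 18, highest other 308), the rad61 double mutant against eco1-W216G (12 with as many as 544, highest other 2250), the interaction of eco1-W216G and the rad61 deletion (12 with as many as 1341, highest other 2866) or the REC8 strain against wild type (7 with as many as 4, highest other 107). Every other split with as many calls kept the later-date groups as labelled and mixed only earlier-date arrays, while most of the 100 mix the later date and had a median of 0 calls. Among the other splits that kept the later date, in the order above, 1 of 9, 2 of 8, 0 of 10, 2 of 7, 1 of 8, 6 of 9, 11 of 11, 11 of 11 and 6 of 9 had as many calls. Such splits keep the real later-date difference in full and are too few for a share under 0.05, so nothing about chance is read from any contrast across dates. The splits with several times the real count, for 18, 101, 544 and 4, all held that difference between the later-date groups, a structure of the samples.

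A reporter probe set outside the tested genes had a mean log2 signal of 14.55 in the rad61 double mutant and 14.43 in the rad61 deletion, against 3.69 in wild type. Another had 9.98 in the REC8 strain with a fob1 deletion and 9.80 in the REC8 strain, against 4.44 in wild type.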

How the results depend on the processing

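Settings that left out a pair of arrays standing apart (rad61 replicate 2 and later-date fob1 replicate 2), those that left out chromosome IX, the rad61 slope without replicate 2 and those with another slope reference were chosen after seeing the data. Of 164 alternatives for counts and slopes, 111 stayed within 1.5 times the count, or 1 jackknife SE of the slope, and 53 moved; for named genes 1600 of 1751 kept their call and 151 lost it, for lists 440 of 519 kept it and 78 lost it, 73 of these with the estimated correlation, where only 2 of 75 kept it. Eco1-W216G against wild type (2506 to 3411) and both of its interactions stayed within 1.5 times in all alternatives run. The slopes ran from 0.0248 to 0.0938 without FOB1, against 0.0531 (SE 0.0461), and from 0.301 to 0.381 without RAD61, against 0.330 (SE 0.0558). The highest without FOB1 used the fob1 deletion of the same date as reference. Mitochondrial ribosomal proteins in the fob1 deletion reversed to a median of -0.055 (adjusted p = 0.245) without the pair of arrays. Camera takes no block, so lists were not run with the date as a random block.

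Without a date term the counts were 1612 for the rad61 deletion, 1944 for the fob1 double mutant, 2412 for the rad61 double mutant and 1401 for the REC8 strain against wild type, and 2908 and 2001 for the fob1 and rad61 double mutants against eco1-W216G. With the date as a random block they were 377, 797, 1586 and 251 against wild type and 1091 for the rad61 double mutant against eco1-W216G. With the replicate number as a block they were 1437 for the fob1 deletion, 199 for the rad61 deletion, 601 and 1433 for the double mutants and 243 for the REC8 strain against wild type. That block also gave 99 and 823 for eco1-W216G in the fob1 and rad61 deletions, 966 for the rad61 double mutant against eco1-W216G and 959 for the interaction with REC8. Deviations of arrays with the same number correlated by a mean of 0.284 on the earlier date (above 0.1 in 35 of 45 pairs), against -0.142 for other numbers, and 17 of 18 arrays correlated best with their own number. On the later date this was 0.161 (7 of 9 pairs), -0.0832 and 6 of 9. On the earlier date the numbers thus point to shared conditions for most arrays, though not in every pair, and the labels name none. The planned fit without the block was kept, so its counts leave this shared part in the spread.

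With only the arrays compared, which leaves fewer samples, the counts were 1 for the fob1 deletion, 1 for the rad61 deletion and 8 for the fob1 double mutant against wild type, 182 for eco1-W216G in the rad61 deletion, 329 for the rad61 double mutant against eco1-W216G, and by limma 0 for the interaction with REC8 (1253 at an unadjusted p under 0.05) and 0 between dates (799 unadjusted). Fewer samples did not lower every count: eco1-W216G had 3309 against wild type and 46 in the fob1 deletion. Later-date fob1 arrays deviated from their group by 0.131, 0.235 and 0.159 (root mean square, log2). Wild-type arrays deviated by 0.0929, 0.0750 and 0.0980. Repeated quantile normalization gave 2 and median centring 2 for the rad61 deletion against wild type, and the trended robust prior 5. Leaving out dim probe sets, the limit set by signal over background, gave 1 for the REC8 strain. Without the pair of arrays the counts were 3 for the rad61 deletion, 152 for the fob1 double mutant and 8 for the REC8 strain against wild type, 906 for eco1-W216G in the rad61 deletion, 1088 for the rad61 double mutant against eco1-W216G and 119 between dates.

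Leaving out each array gave 2.2e+02 to 1313 for the fob1 deletion, 1 to 2.2e+02 for the rad61 deletion, 21 to 429 and 534 to 1327 for the fob1 and rad61 double mutants and 2 to 172 for the REC8 strain against wild type. It gave 12 to 30 and 183 to 553 for eco1-W216G in the fob1 and rad61 deletions, 1187 to 1949 and 309 to 955 for the double mutants against eco1-W216G, 64 to 872 for the interaction with REC8 and 40 to 447 between dates. For all of these the cause was not tested.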

Other observations

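The comparisons of rad61 replicate 2 and of reporter probe sets were chosen after the results were seen; the list and chromosome tests were not. Other gene groups moved with eco1-W216G against wild type. Of 48 meiotic genes 25 rose and 7 fell (26 and 7 adjusted over the list alone), with a median of 0.29 (adjusted p = 1.7e-05, and adjusted p = 0.269 with an estimated correlation). Of 32 cell wall integrity genes 21 rose and 4 fell, the same adjusted over the list alone (adjusted p = 0.000101, and adjusted p = 0.391 with an estimated correlation). Seripauperins, cell wall proteins of the PAU family, rose in 8 of 13 cases (8 adjusted over the list alone) with a median of 0.59 (adjusted p = 0.00163, and adjusted p = 0.391 with an estimated correlation).

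By chromosome, genes of chromosome I were higher in eco1-W216G against wild type by a median of 0.19 (adjusted p = 0.0427 with an estimated correlation), in the mutant in the rad61 deletion by 0.14 (adjusted p = 0.00355) and in the rad61 double mutant against wild type by 0.24 (adjusted p = 0.0298). Chromosome IX genes differed by 0.29 in the rad61 deletion against wild type, with adjusted p = 0.983 with an estimated correlation, and in that group the genes were higher in replicate 2 by 0.82. A set of 4 reporter probe sets of the same sequence lay between 3.45 and 4.74 (log2) in rad61 replicate 2 and the 3 arrays of the fob1 double mutant, and between 8.33 and 13.37 in the other 23 arrays. Another, of a different sequence, lay between 4.52 and 4.87 in those 4 arrays and between 9.55 and 10.57 in the others.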
